A study of Mus musculus with 16 samples.

How the data were processed

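Libraries were made with the 10x Chromium 3′ protocol with version 2 chemistry, per the labels' protocols, which captures the 3′ end of transcripts in single cells and tags each molecule with a UMI. The 16 records of the series, 8 for each group, are parts of 2 libraries, since the design text names 2 samples and 1 matrix was deposited for each group. The control group carries the labels minus TAM and KMT9wt/wt and the knockout group plus TAM and KMT9ko/ko. The labels do not spell out TAM, and day 5 appears only in the names of the deposited tables. The deposited values are UMI counts per gene and cell, made by the authors with Cell Ranger 3.1.0, per the file headers, on the mm10 genome, per the submitters' processing notes. The counts are whole numbers, were not normalized and cover barcodes of 500 or more UMIs. The annotation release behind them is not given in the sources used here. Of 31053 gene identifiers, 31011 were found in GENCODE release M21, which was used for positions, transcript lengths and overlapping genes, and 35 symbols stand on more than 1 identifier.

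Cells with at least 1000 genes, at least 2000 UMIs and at most 20% mitochondrial UMIs were kept. This removed 931 of 3618 control barcodes (25.7%) and 579 of 2078 knockout barcodes (27.9%). Doublet scores were computed in each library with Scrublet as included in scanpy 1.11.5. Its automatic threshold marked only 1 and 4 cells (0.0372% and 0.267%), so the cells with the highest scores were removed instead, 0.8% for each 1000 cells, which came to 58 and 18. The kept cells held 95.0% and 96.1% of all UMIs of their matrices and 17902 and 17436 detected genes. Ribosomal protein genes took a median of 22.6% and 23.5% of the UMIs of a cell.

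Raw counts were summed over the kept cells of each library and scaled to CPM over all genes. Genes with 10 or more CPM in at least 1 library were called measured. A ratio is knockout over control without a pseudocount, and a gene with no UMI in 1 library took a floor of 3 counts. A gene was counted as higher or lower at a ratio of 1.5-fold or more, a size threshold and not a test. Poisson intervals for CPM, conditional binomial intervals for ratios and Clopper-Pearson intervals for shares are exact, at 95%, and cover counting error only. Where a count was 0, the limit of a share given in the text is 3 counts of the total and not the exact bound. An upper limit in CPM is the exact Poisson bound.

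Gene lists were fixed before the data were examined, as were the main settings, the other settings named as chosen beforehand and the rule for named genes. They cover KMT9 and TRMT112 partners, intestinal stem cell, Wnt, fetal-like and YAP, S phase, G2 and M phase, colonocyte, goblet, enteroendocrine, tuft, Paneth-like, Reg and antimicrobial, epithelial, immune, fibroblast and endothelial genes. They further cover p53, apoptosis, cholesterol, fatty acid synthesis and oxidation, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, ribosome biogenesis, tRNA synthetase and amino acid response, endoplasmic reticulum chaperone, immediate early, heat shock, NRF2, interferon, MHC class I and class II, Notch, BMP and TGF-beta, MAPK and EGFR feedback, estrogen and xenobiotic, epithelial to mesenchymal transition, lysosome and chromatin genes. The median log2 ratio of a list with 5 or more measured members was placed among 10000 random lists of the same size, matched on mean CPM in 20 bins, and was called outside its random range beyond the middle 95%. Of 35 lists with a percentile, 1.75 would lie outside by chance if lists were random draws. The rule for named genes took N6amt1 and Trmt112, the 12 largest and 12 smallest ratios among genes with 50 or more CPM, up to 4 members per list with the largest ratios in either direction, a set of fixed genes and up to 5 leading genes per cluster, leaving unnamed predicted genes out of the 24 extreme ones. A few genes that this rule names are not reported here.

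For shares of cells with a UMI, each cell was thinned at random to 5000 UMIs. For clustering, counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 were used without integration of the libraries (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). A cluster took the name of a class, from markers fixed before the data were examined, when 3 or more of them were 2-fold or more above the other cells at 10 or more CPM, when 2 or more stood among its 10 leading genes, and when it had more of them than of any other class. These numbers were set after the data were seen. List medians within a class were computed where each library had at least 100 cells.

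Alternatives chosen beforehand were no cell filter and a stricter one (2000 genes, 10% mitochondrial UMIs), no doublet removal, other minimum CPM (5, 50, a mean of 10, none), a 2-fold threshold, trimmed mean factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios size factors, totals without mitochondrial and ribosomal protein genes, each cell weighted alike, random lists without matching, only cells with few G2 and M phase UMIs, thinning to 3000 or 10000 UMIs or none, resolutions of 0.4 and 1.2, 20 components, clustering without cell cycle genes and clustering of each library alone. Alternatives added after seeing the data left out cells whose barcode occurs in both matrices, the smaller copies of such barcodes, low-depth clusters or colonocyte-like clusters, took ratios relative to the tenth of transcript length, or used the cycling-like class of the clustering without cell cycle genes.

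The steps were tested on simulated data for the knockout over control comparison, with 7614 genes drawn at the real depths. Of 50 genes changed at each of 4 sizes (3-fold and 2-fold, up and down), 100% passed the 1.5-fold threshold, and 0 of 7414 unchanged genes did. The exact ratio interval held the simulated ratio in 96.8% of cases, and 8 of 100 random lists fell outside the middle 95%. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.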

Results

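Single-cell transcriptomes were collected from organoids grown from mouse colon tumours of the AOM/DSS model, in which the carcinogen azoxymethane is combined with dextran sodium sulfate, an irritant of the colon. Organoids are epithelial cultures that grow in 3 dimensions from tissue stem cells. The labels give passage 14 and name a control with wild-type KMT9 alleles (minus TAM) and a knockout of both KMT9 alleles (plus TAM). The 8 records of each group were taken as parts of 1 library from the series design text, which gives n = 1, and whether separate cultures stand behind them is not given in the sources used here. KMT9 is a histone methyltransferase made of KMT9alpha, the product of N6amt1, and its partner TRMT112. By its title, the series asks how KMT9 bears on growth and stemness of colorectal cancer. The deposited matrices held 3618 barcodes and 72223578 UMIs (unique molecular identifiers, 1 per captured RNA molecule) in the control library, and 2078 barcodes and 38860718 UMIs in the knockout library. After filtering, 2629 control and 1481 knockout cells remained, with 68605296 and 37358097 UMIs. Median depth was 24603 and 24184 UMIs per cell, median genes per cell 4858 and 4704, and the median mitochondrial share 2.88% and 2.87%. With 1 library per group no test across replicates was possible, and all differences describe these 2 libraries. Every interval given is a 95% interval for counting error only. As the labels pair the knockout with plus TAM, effects of TAM itself cannot be told apart from those of the knockout.

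The first comparison asked whether the targeted gene was lower in the library labelled knockout. N6amt1 (ENSMUSG00000044442) stood at 34.1 CPM (counts per 1000000 UMIs) in the control and 6.13 CPM in the knockout library, 5.56-fold lower, with a log2 ratio of -2.47 (interval -2.68 to -2.28). These values rest on 2338 and 229 UMIs. Of all kept cells, 52.4% (interval 50.4 to 54.3) held an N6amt1 UMI in the control library and 13.4% (11.7 to 15.2) in the knockout library. In cycling-like cells, a group defined by clustering, N6amt1 stood at 29.9 against 3.93 CPM. The level left in the knockout library was uneven, with 9.62 CPM in cluster 4, 9.60 CPM in cluster 5 and 10.9 CPM in cluster 6, whose control cells held 43.2, 39.7 and 27.6 CPM. Trmt112, which encodes the partner subunit, stood at 208 and 165 CPM, a log2 ratio of -0.34. Ltn1, a ubiquitin ligase gene beside N6amt1 on the same chromosome, was at 9.15 and 8.91 CPM. N6amt1 lies on chromosome 16 from 87354185 to 87368742 on the plus strand of mm10, with 6 exons, the last from 87367465 to 87368742. Which exon was deleted is not given in the sources used here, and the tags of this assay come from the 3′ end of transcripts. If the tags lie outside the deleted part, the value for N6amt1 does not measure the deletion itself, although its direction was that of the label.

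**Figure D1:**
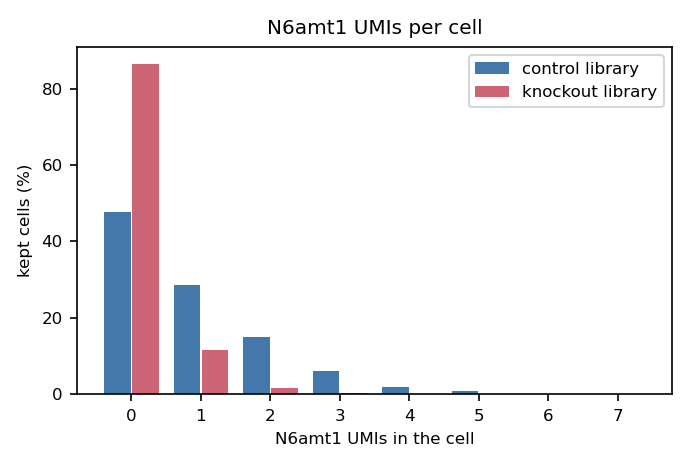
N6amt1 UMIs per cell (x axis) against the percentage of kept cells (y axis) in the control library (2629 cells) and the knockout library (1481 cells). Of the knockout cells, 1283 held no N6amt1 UMI and 198 held 1 or more.

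The second comparison asked which genes differed most between the libraries. Among genes with 50 or more CPM in at least 1 library, with unnamed predicted genes left out, the largest ratios toward the knockout library belonged to Sprr1a, a cornified envelope gene induced in injured and fetal-like gut epithelium, at 13.1 against 231 CPM (17.6-fold, log2 ratio 4.14, interval 4.04 to 4.24), and to the chemokine gene Ccl5, at 7.91 against 74.9 CPM (9.47-fold), with a UMI in 0.844% and 2.81% of cells thinned to 5000 UMIs. Among the same genes, the largest ratios toward the control library belonged to Avil, an actin-binding villin family member, at 86.0 against 17.5 CPM (4.90-fold lower), and to Chchd10, which encodes a mitochondrial protein, at 630.3 against 156 CPM (4.04-fold lower, log2 ratio -2.02, interval -2.06 to -1.98). Cdx2, the transcription factor of intestinal identity, stood at 93.3 against 25.3 CPM. Ascl2, a transcription factor of intestinal stem cells, stood at 116 against 38.1 CPM. Clu, a marker of revival stem cells, stood at 81.2 against 322 CPM. In the knockout library 9144 of its 12026 UMIs lay in colonocyte-like cells, a group defined by clustering. In the control library 1263 of its 5573 UMIs did. After thinning to 5000 UMIs, 522 of 2487 control and 407 of 1387 knockout cells held a Clu UMI, so the CPM ratio was not spread evenly over cells. Among cells whose barcode occurred in 1 matrix alone, Sprr1a stood at 12 against 138 CPM and Clu at 82.6 against 215 CPM.

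The 12 genes with the smallest ratios also held the following. Atf5 and Trib3, which are induced when amino acids are short, had log2 ratios of -1.79 and -1.78. Cth, an enzyme of cysteine synthesis, had a log2 ratio of -1.39. The mitochondrial protease gene Lonp1 stood at 174 against 58.0 CPM, and Coa7, an assembly factor of the respiratory chain, at 73.3 against 26.8 CPM. The others were Ppp1r1b (DARPP-32, an inhibitor of protein phosphatase 1; log2 ratio -1.66), Rpp25l (-1.59) and Cyb5r1 (-1.44). Of the 12 genes with the largest ratios, Krt90, a keratin gene, stood at 12.2 against 87.6 CPM, the skin protease gene Asprv1 at 41.5 against 170.2 CPM, the metallothionein gene Mt4 at 141 against 544 CPM, and Plat, tissue plasminogen activator, at 73.1 against 275 CPM. Log2 ratios were 2.38 for Spp1 (osteopontin), 2.31 for Bmp2 and 1.97 for the neutrophil chemokine gene Cxcl5. Car1, a colonocyte carbonic anhydrase, stood at 54.9 against 257 CPM, but among cells whose barcode occurred in 1 matrix alone it was lower in the knockout library, at 48.1 against 14.2 CPM. That choice left out 167 of 2629 control and 324 of 1481 knockout cells. In 318 of these knockout cells the control copy was the smaller one, and 93 of them lay in cluster 7, a colonocyte-like cluster. Rnd1, a small GTPase gene, stood at 17.5 against 68.2 CPM. Avil, Chchd10, Atf5 and Rpp25l overlap another annotated gene on the opposite strand, and whether the counting used strand is not given in the sources used here.

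**Figure D2:**
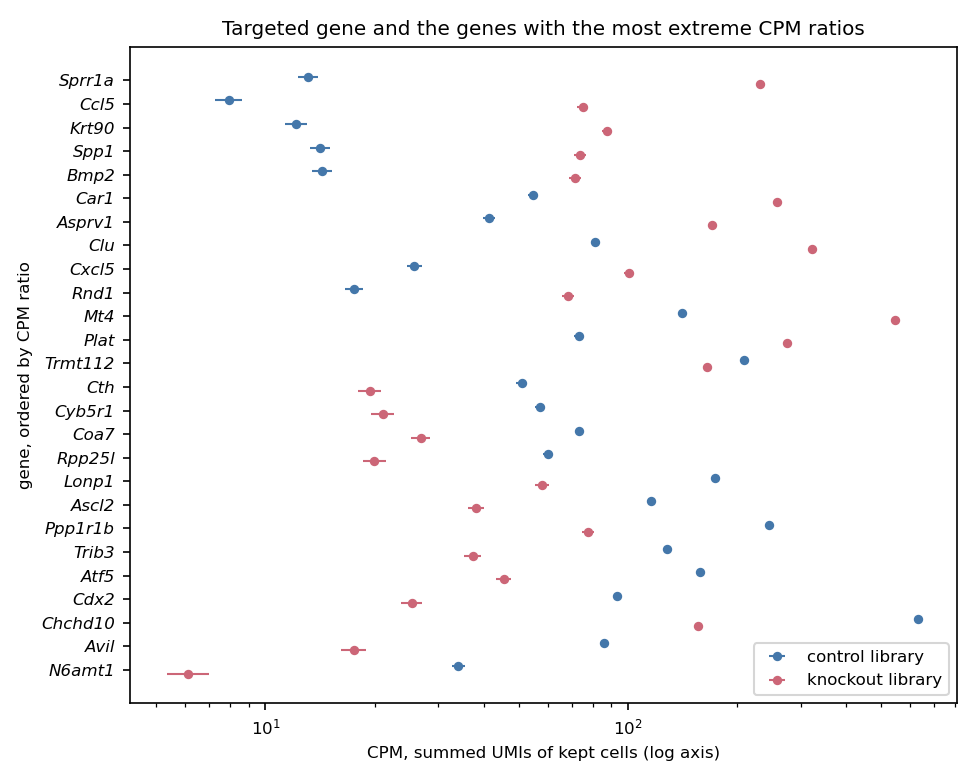
CPM of N6amt1 and of the 12 genes with the largest and the 12 with the smallest ratio in the control and knockout libraries (log axis, 1 point per library, genes ordered by ratio). Sprr1a stands at 13.1 and 231 CPM, and Avil at 86.0 and 17.5 CPM.

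Of 7912 genes with 10 or more CPM in at least 1 library, 638 were 1.5-fold or more higher in the knockout library, 844 were 1.5-fold or more lower and 6430 were neither. These numbers sort genes by size and do not come from a test. Longer transcripts had higher log2 ratios (Spearman's coefficient 0.242 and Pearson's r 0.160 across 7833 genes, which are not independent replicates). Relative to the median of genes of like transcript length, 688 genes were higher and 607 lower by 1.5-fold.

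Some genes were fixed before the data were examined and are given whatever their values. Lgr5, a Wnt-responsive stem cell receptor gene, stood at 4.90 against 2.28 CPM (log2 ratio -1.11, interval -1.47 to -0.76), and Smoc2 at 157 against 107 CPM. Axin2, a direct Wnt target, was at 101 against 115 CPM, and Myc at 107 against 129 CPM. Ly6a, which marks fetal-like and regenerating epithelium, was at 1762 against 1878 CPM, and Cdkn1a, which encodes the p21 cell cycle inhibitor, at 713 against 607 CPM. The proliferation genes Mki67 and Pcna had log2 ratios of -0.62 and -0.45, and Top2a one of -0.26. Krt20, a keratin of differentiated colonocytes, stood at 5.60 against 22.6 CPM, and at 5.90 against 14.0 CPM among cells whose barcode occurred in 1 matrix alone. Secretory markers were near the floor, with Muc2 at 0.962 against 1.5 CPM, Chga at 0.394 against 0.830 CPM and Lyz1 at 0.714 against 0.428 CPM. Dclk1, a tuft cell marker, had a UMI in 0 of 2629 control cells and 0 of 1481 knockout cells, which allows shares of cells with a UMI of up to 0.114% and 0.203%.

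The third comparison asked which of 41 gene lists, fixed before the data were examined, stood apart between the libraries. The medians of lists of DNA replication, mitosis, ribosome assembly and amino acid supply lay below those of random lists. Those of 14 lists lay above. Among them were lists of mucosal defence, Wnt targets, interferon response, immediate early genes, and glycolysis and hypoxia. Others were of BMP, Notch and MAPK signalling and a few epithelial to mesenchymal transition genes. The S phase list had a median log2 ratio of -1.16, and 32 of its 35 measured members were 1.5-fold or more lower and 0 higher. Its members with the largest ratios were Ung (-1.65), Rad51ap1 (-1.47), Prim1 (-1.46) and Dscc1 (-1.42), genes of DNA repair and replication. The G2 and M phase list had a median of -0.70, with 28 of 40 members lower, among them Ckap2 (-1.60), Ckap2l (-1.51), Dlgap5 (-1.07) and Gtse1 (-1.07), all of the mitotic spindle or G2 phase. Medians are described by their percentile among 10000 random lists of the same size matched on mean CPM, and both of these lay at percentile 0. Control cells weighted to the knockout library's share of cycling-like cells, a group defined by clustering, gave a median of -0.26 for the S phase list and -0.72 for the G2 and M phase list. Weighted to the knockout library's shares of all 14 clusters, they gave -1.05 and -0.98.

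Ribosome biogenesis and MYC target genes had a median of -0.56 (percentile 0), with 13 of 30 lower, led by Rrs1 (196 against 89.6 CPM), the spermidine synthase gene Srm (177 against 88.1 CPM), Nop2 (-0.94) and Nolc1 (-0.84). The tRNA synthetase and amino acid response list had a median of -0.45 (percentile 0), with 11 of 28 lower and 1 higher. Besides Atf5 and Trib3 it was led by Yars (131 against 54.7 CPM) and Wars (86.4 against 41.2 CPM), which load tyrosine and tryptophan onto tRNA. Nuclear-encoded oxidative phosphorylation genes had a median of -0.22 (percentile 0.02), with only Cox5a (-0.69) and Uqcrq (-0.60) of 44 lower by 1.5-fold and 0 higher. The next largest ratios were those of Atp5b (-0.52) and Ndufs3 (-0.51).

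In the opposite direction, 4 of 5 measured epithelial to mesenchymal transition genes, of 17 on the list, were higher, with a median of 1.0 (percentile 100). Among these were fibronectin Fn1 (8.05 against 44.5 CPM), vimentin Vim (166 against 335 CPM) and the laminin gene Lamb3 (52.3 against 87.5 CPM). The epithelial gene Cdh1, on another list, was not lower, at 91.1 against 136 CPM. Reg and antimicrobial genes had a median of 0.60 (percentile 100), with 7 of 14 higher, such as Cxcl5, Slpi (1.09) and Tnfaip3 (0.87). Its 1 lower member was Pigr, the receptor that carries antibodies across epithelium (12.6 against 2.54 CPM). BMP and TGF-beta targets had a median of 0.46 (percentile 99.9), with 4 of 10 higher, namely Bmp2, Skil (1.27), Bambi (0.98) and Smad6 (0.79). The Notch pathway had a median of 0.45 (percentile 99.7), with 2 of 9 higher, Hes1 (559 against 1036 CPM) and Notch2 (0.64), beside Nrarp (0.54) and Dtx4 (0.51). MAPK and EGFR feedback genes had a median of 0.41 (percentile 100), with 6 of 19 higher and 2 lower, among them Etv5 (1.26), Spry2 (1.24), Egfr (1.08) and the EGFR ligand Areg (679 against 373 CPM).

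The colonocyte and enterocyte list had a median of 0.40 (percentile 100), with 7 of 19 higher and 3 lower. The membrane mucin gene Muc3 stood at 1.43 against 18.4 CPM (1.19 against 2.71 CPM among cells whose barcode occurred in 1 matrix alone), Car1 and Krt20 at the values above, and the fatty acid binding protein gene Fabp2 at 10.1 against 3.24 CPM. This median turned to -0.56 without the colonocyte-like clusters and to -0.38 without cells whose barcode occurred in both matrices. Fetal-like and YAP targets had a median of 0.26 (percentile 99.9), with 7 of 21 higher, led by Sprr1a, Spp1, Clu and Amotl2 (0.87), and 1 lower, and the median turned to -0.066 without the colonocyte-like clusters. Wnt targets had a median of 0.27 (percentile 99.9), with 5 of 19 higher and 2 lower. Their largest ratios went both ways, with the Wnt antagonist Dkk2 at 1.65 against 14.7 CPM, the matrix protease Mmp7 at 215 against 443 CPM, cyclin D1 (Ccnd1) at 555 against 284 CPM, and Ascl2 as above.

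Immediate early genes, which also respond to cell dissociation, had a median of 0.35 (percentile 100), with 3 of 17 higher, Socs3 (1.27), Dusp1 (0.99) and Fosb (0.69), followed by Nr4a1 (0.56). Interferon response genes had a median of 0.32 (percentile 99.9), with 6 of 21 higher and 1 lower, among them Ifi27l2a (7.40 against 33.4 CPM), Rsad2 (1.10), Zbp1 (1.09) and Usp18 (1.0). Fatty acid synthesis genes had a median of 0.43 (percentile 99.5), with the desaturase genes Scd1 (0.77) and Scd2 (0.71) the 2 of 9 that were higher, beside Me1 (0.50) and Acly (0.43). Glycolysis and hypoxia genes had a median of 0.20 (percentile 99.8), with 7 of 22 higher, including hexokinase Hk2 (32.0 against 69.8 CPM), Ndrg1 (0.88), P4ha2 (0.84) and Egln3 (0.75). Lysosome and autophagy genes had a median of 0.16 (percentile 99.5), with 2 of 26 higher and 2 lower, Lamp2 (0.69) and Ulk1 (0.59) against the cathepsin gene Ctsb (-0.78) and Gaa (-0.69). Heat shock genes had a median of 0.15 (percentile 98.2), with 0 of 13 past 1.5-fold and Hspa1b (0.58), Hspb1 (0.55), Bag3 (0.43) and Hsp90aa1 (-0.26) farthest from 0. The heat shock list lay within its random range under 4 alternatives, the Notch and fatty acid synthesis lists without a filter on low genes, the BMP list at 50 or more CPM and the lysosome list without cells of a shared barcode. In cells with few G2 and M phase UMIs the G2 and M phase median was -0.26, within its random range, and the S phase median -0.75, and relative to genes of like transcript length the oxidative phosphorylation median was -0.086, both still outside.

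**Figure D3:**
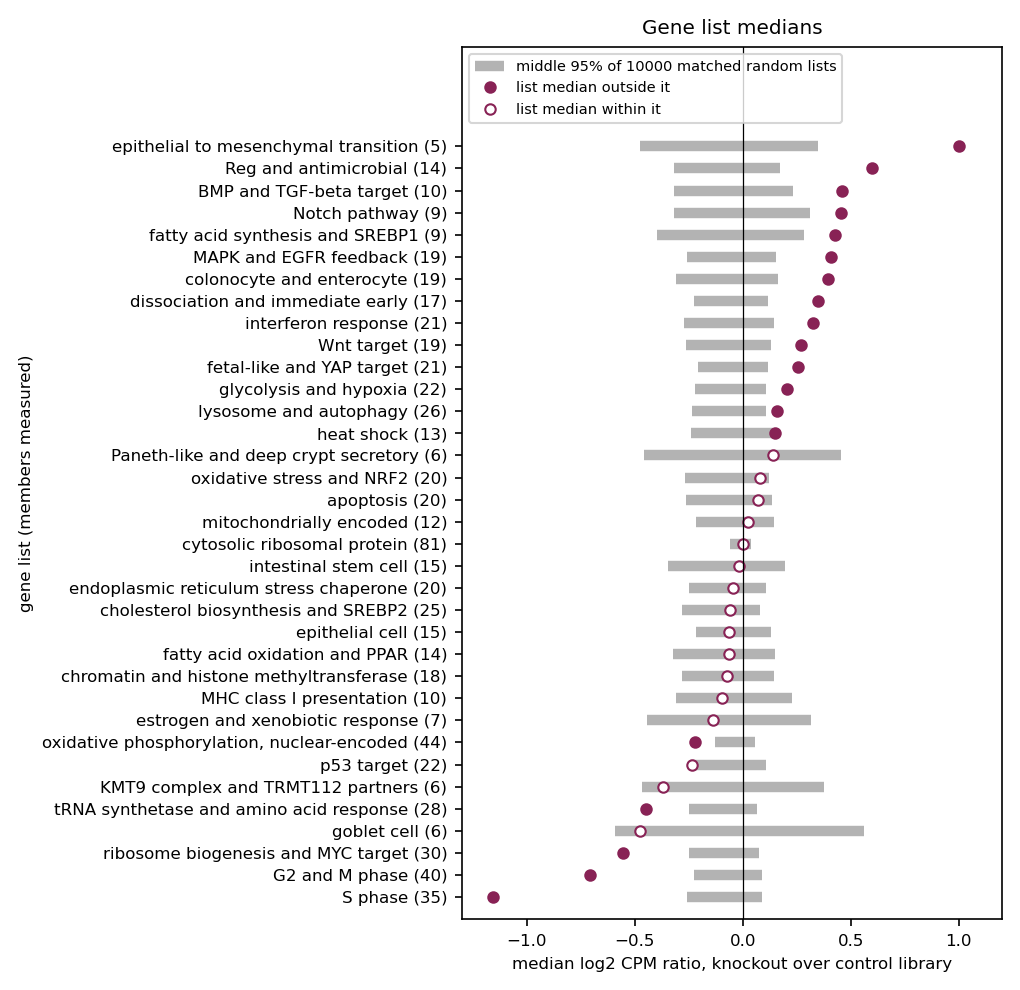
Median log2 ratio of CPM, knockout over control library (x axis), of the 35 gene lists with 5 or more measured members (number in parentheses), with grey bars for the middle 95% of 10000 matched random lists. The S phase list stands at -1.16, and 5 lists lie below and 14 above their random range.

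The intestinal stem cell list lay within its random range, with a median of -0.02 (percentile 67.9). Of its 15 measured members 3 were higher and 3 lower, with Ascl2, Cdca7 (54.2 against 20.7 CPM) and Lrig1 (-0.81) on the lower side and Zbtb38 (36.4 against 82.7 CPM) on the higher side. The epithelial cell list had a median of -0.07, with the intestinal transcription factors Cdx2 and Cdx1 (55.3 against 25.8 CPM) as its 2 lower members of 15, beside Cdh1 (0.58) and Hnf4a (-0.40). The list of KMT9 and other TRMT112 partners had a median of -0.37 (percentile 7.06), and N6amt1 was its 1 lower member of 6, followed by Bud23 (-0.55) and Trmt11 (-0.40). p53 targets had a median of -0.24 (percentile 2.85), with 3 of 22 lower, Ckap2, Bbc3 (-0.76) and Gdf15 (445 against 289 CPM), followed by Perp (-0.56). Goblet cell genes had a median of -0.48 (percentile 6.0) over 6 members, with Galnt12 (-0.94) and Agr2 (-0.69) lower, beside St3gal6 (0.54) and Reg4 (-0.52). Over the 6 Paneth-like and deep crypt secretory genes measured, the median was 0.14, with Itln1 (-2.16) and Ang4 (-1.83) lower and Pnliprp2 (2.02) and Mmp7 higher. Chromatin and histone methyltransferase genes had a median of -0.07, with Dnmt1 (-0.85), Suv39h1 (-0.61) and Prmt5 (-0.61) lower and Kdm5b (0.68) higher among 18.

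The remaining lists with a percentile also lay within their random range, and their members with the largest ratios were as follows. Cytosolic ribosomal protein genes had a median of 0.00 over 81 members, of which Rpl39 (0.70), Rps28 (0.66) and Rpl36a (0.65) were higher, followed by Rpl37a (0.51). Mitochondrially encoded genes had a median of 0.02, with mt-Nd3 (0.61) the 1 of 12 past 1.5-fold, ahead of mt-Atp8 (0.50), mt-Nd4l (0.29) and mt-Co3 (-0.24). Cholesterol synthesis genes had a median of -0.06 over 25 members, of which 2 were lower, among them Stard4 (-0.62), followed by Lss (-0.53) and Fdft1 (-0.48). Fatty acid oxidation genes had a median of -0.07, with Acot2 (-1.40), Ech1 (-0.67) and Acaa2 (-0.64) lower among 14, then Hadhb (-0.40). The estrogen and xenobiotic response list had a median of -0.14 (percentile 34.4), with Cyp1a1 (40.8 against 13.3 CPM) and Aldh1a1 (-1.08) lower among 7, beside Cyp2b10 (-0.45) and Cyp3a13 (0.15). Medians were 0.07 for apoptosis genes (Birc3 1.02, Bik 0.90, Bbc3 -0.76, Bcl2 0.62) and -0.04 for endoplasmic reticulum chaperones (Herpud1 0.68, Dnajb9 0.49, Pdia4 -0.48, Sel1l -0.46). Medians were 0.08 for NRF2 targets (Gsta1 1.98, Gsta3 -1.39, Hmox1 0.72, Slc7a11 0.70) and -0.10 for MHC class I presentation (Tapbp 0.62, Erap1 -0.52, B2m 0.50, Tap1 -0.44).

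Markers of other cell types were scarce in both libraries. Ptprc, found on all white blood cells, had 4 UMIs in the control and 1 in the knockout library, and the fibroblast collagen gene Col1a1 had 1 and 0. The epithelial genes Epcam and Krt8 stood at 899.5 against 951 CPM and 2941 against 3334 CPM. Too few members were measured for a percentile in 6 lists. In these, the measured immune genes were Cd68 (0.47) and Cd14 (0.22), the fibroblast gene was Vim, and the endothelial genes were Cdh5 (1.24) and Egfl7 (-0.53). MHC class II presentation was represented by Cd74 (0.37), enteroendocrine cells by Cpe (7.03 against 34.7 CPM), and tuft cells by Avil, Ptgs1 (0.81), Cd24a (0.27) and Espn (-0.19).

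The fourth comparison asked in what share of cells a gene was detected, with each cell thinned to 5000 UMIs. This left 2487 control and 1387 knockout cells, and 142 and 94 shallower cells were left out. Ascl2 had a UMI in 34.1% of control cells (interval 32.2 to 36.0) and 14.2% of knockout cells (12.4 to 16.2), Mki67 in 8.12% (7.08 to 9.27) and 4.69% (3.64 to 5.93), Top2a in 16.1% and 9.30%, and Smoc2 in 41.7% and 32.9%. Pcna was detected in 32.6% and 25.7% of cells, Axin2 in 38.0% and 41.7%, Ly6a in 84.2% and 82.9%, Cdkn1a in 85.2% and 82.7%, N6amt1 in 16% and 3.24%, and Trmt112 in 63.4% and 57.9%. Of the genes with the most extreme ratios, Sprr1a was detected in 3.02% and 18.7% of cells, Chchd10 in 88.2% and 48.4%, and Trib3 in 35.7% and 13.2%. Unthinned, the shares were 66.7% and 36.0% for Ascl2, 22.1% and 13.2% for Mki67, 33.7% and 19.0% for Top2a, and 8.67% and 35.4% for Sprr1a.

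In colonocyte-like cells (mostly cluster 9 in the control and cluster 7 in the knockout library), which should lack proliferation genes, thinned shares for Mki67 were 2.56% in the control and 0.515% in the knockout library, and for Top2a 3.08% and 2.06%. The unthinned median depth of those cells was 25910 and 28768.5 UMIs. Lgr5 was detected in 2.05% of control and 1.08% of knockout cells, against 2.56% and 0.515% of colonocyte-like cells. As many colonocyte-like cells of the control library held Ascl2, another stem cell marker, they are no clean reference, and whether the Lgr5 share lies above background is left open. Krt20 was detected in 2.45% and 4.11% of cells, against 3.30% (interval 1.86 to 5.38) and 2.36% (0.490 to 6.75) of cycling-like cells, whose unthinned median depth was 30818 and 34382 UMIs. Its share over all cells was thus not clearly above the cycling-like one, while in colonocyte-like cells it was 5.64% (2.85 to 9.87) and 9.28% (5.59 to 14.3). Olfm4, another stem cell marker, was detected in 0 cells of either library after thinning, which allows up to 0.121% and 0.216%. Tff3 was detected in 1.17% and 0.360% of cells, and Muc2, Chga and Lyz1 in under 1% of cells of each library. Ascl2 was more frequent in the colonocyte-like cells of the control library (57.9%, interval 50.7 to 65.0) than in its cycling-like cells (36.3%, 31.8 to 40.9).

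The fifth comparison asked which groups of cells each library held. Clustering of both libraries together gave 14 clusters, and 1 of them, led by the mitotic genes Nusap1, Ube2c, Hmmr and Ccnb1 and by Hist1h2ap, was cycling-like. Cycling-like cells made up 17.5% of control cells (460 of 2629, interval 16.1 to 19.0) and 8.58% of knockout cells (127 of 1481, interval 7.20 to 10.1). With the S phase and G2 and M phase genes left out of the clustering, the shares were 17.5% and 7.36%.

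Clusters 7 and 9 carried markers of differentiated colonocytes. Cluster 7, led by Clca4a, Muc3, Car1 and Gsta1, held 31 control and 198 knockout cells, while cluster 9, with Aqp1, Cldn15, Fabp2 and Lypd8 among its leading genes, held 171 control and 9 knockout cells. Since different clusters hold this class in each library, its size is not compared. Of the knockout cells in cluster 7, 47.0% had a barcode that also occurred in the control matrix. Most other large clusters came mainly from 1 library, and such a cluster may be that library and not a cell type. Cluster 0 (671 control and 34 knockout cells) was led by the hedgehog gene Shh, Tmed6, Reg4, Tgfbi and Sectm1b, and cluster 2 (530 and 9) by Golga7b, Ifit1bl1, Kcne3, Ung and Timp3. Cluster 3 (69 and 405) was led by Tmprss11d, Asprv1, Ppbp, Spp1 and Krt16, and cluster 4 (69 and 310) by Cxcl14, Lce1h, Cadps, Gm29865 and Rhoj. Cluster 6 (98 and 185) was led by Prss56 and the pancreatic lipase family genes Pnliprp1 and Pnliprp2 with Tpsb2 and Thbs2, and cluster 10 (139 and 12) by Cav1, Ccl20, Clca3b, Dnah7b and Tm4sf1. Cluster 5 (199 and 85) was led by Rbp4, Cited1, Itln1, Ifi27l2a and Slc16a3. Of the rest, cluster 13 (11 and 1) was led by Ang4, Serpina1b, Tff3, Serpina1c and Chga, and clusters 8, 11 and 12 were of low depth, with medians of 4060, 5734 and 2563 UMIs. A naming rule set after the data were seen left unnamed some clusters with 3 or more markers of a class. These were cluster 0 with 3 of 26 goblet markers (25.5% of control and 2.30% of knockout cells) and cluster 4 with 3 of 21 stem cell markers (2.62% and 20.9%). Cluster 10 had 7 fetal-like markers (5.29% and 0.810%) and cluster 13 had 11 enteroendocrine markers (0.418% and 0.0675%). Among the 10 leading genes stood 1 such marker in clusters 0, 10 and 13 and 0 in cluster 4. So few markers do not show that the cells of clusters 0 and 4 are goblet or stem cells. Clusters 8 (5.78% and 4.46%) and 12 (0.190% and 0.945%), both of low depth, held cycling markers and were left unnamed too.

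**Figure D4:**
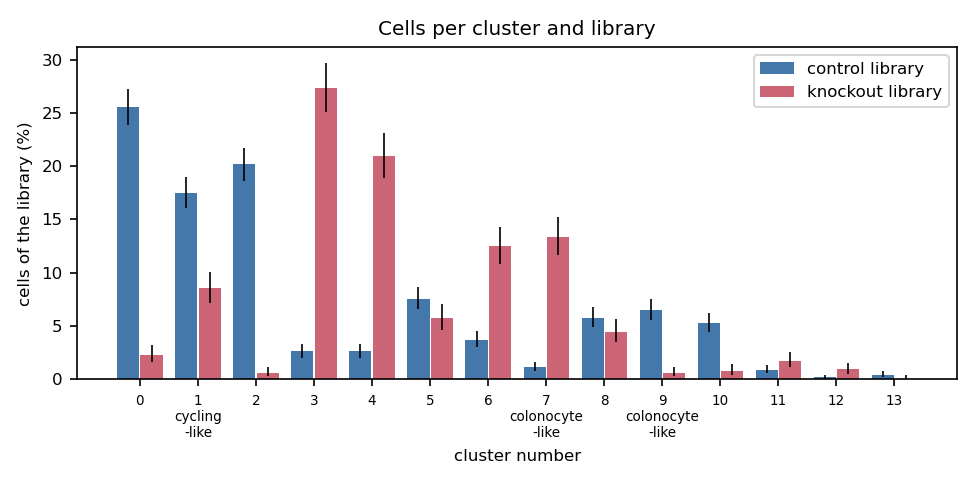
Percentage of the kept cells of each library (y axis) in each of the 14 clusters (x axis), with exact binomial 95% intervals for counting error. Cluster 1, the cycling-like one, holds 17.5% of control and 8.58% of knockout cells, and clusters 0 and 2 are mostly control cells while clusters 3, 4 and 7 are mostly knockout cells.

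The sixth comparison asked whether differences between whole libraries were also found among cells of 1 class. In the cycling-like cells, where the same cluster was compared, Chchd10 stood at 609 against 142 CPM, Trib3 at 242 against 42.3 CPM, Atf5 at 186 against 56.9 CPM, Lonp1 at 274 against 82.8 CPM and Avil at 125 against 21.7 CPM. Cdx2 was at 81.5 against 33.5 CPM and Ascl2 at 110.1 against 63.4 CPM. Spp1 was at 29.0 against 108 CPM, Bmp2 at 12.3 against 34.2 CPM and Sprr1a at 8.0 against 25 CPM, while Clu, at 44.3 against 54.6 CPM, was nearly level. Ccl5 and Car1 went the other way there by CPM, at 14.9 against 3.70 CPM and 7.87 against 3.47 CPM, but on few cells. After thinning, Ccl5 had a UMI in 6 of 455 control and 4 of 127 knockout cells (1.32% and 3.15%), so its share did not go the other way. Car1 had one in 11 of 455 and 1 of 127 cells. Ribosome biogenesis genes had a median log2 ratio of -0.38 (percentile 0.10), with 11 of 30 lower, and tRNA synthetase and amino acid response genes one of -0.32 (percentile 0.50), with 10 of 28 lower and 2 higher. BMP and TGF-beta targets had a median of 0.80 and Wnt targets one of 0.41, both at percentile 100. Reg and antimicrobial genes had a median of 0.53 (percentile 100), immediate early genes one of 0.21 (percentile 99.4), Notch genes one of 0.29 (percentile 97.6) and glycolysis and hypoxia genes one of 0.43 (percentile 100). Of the lists that stood apart between whole libraries, the following lay within their random range there. Medians were 0.19 (percentile 91.1) for epithelial to mesenchymal transition genes, 0.13 (95.6) for MAPK and EGFR feedback, 0.10 (95.7) for interferon response, 0.07 (90.7) for fetal-like and YAP targets, 0.23 (96.5) for fatty acid synthesis, -0.04 (51.3) for heat shock, -0.11 (53.6) for lysosome and autophagy and -0.06 (27.3) for oxidative phosphorylation genes. The colonocyte and enterocyte list went the other way, with a median of -0.87 (percentile 0) and 9 of 13 lower. The S phase and G2 and M phase genes help to define this cluster, so their medians there, -0.51 and 0.13, are not read as differences.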

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

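The tests on barcodes found in both matrices, on unrecombined cells, on control molecules under the knockout index, on the shares of cycling-like cells and of all clusters, on other differences between the cultures and on loss of KMT9alpha were chosen only after the result was seen, and so was the use of transcript length as an alternative.

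The barcode lists, which no comparison uses as data, shared 498 barcodes between the 2 libraries, an overlap outside the measurement, in which the filter removed the control copy alone 319 times and the knockout copy alone 163 times. Unrelated cells that drew the same barcode would resemble each other no more than random cells do, but the smaller copy correlated better with its own barcode than with a random cell of like depth in 98.8% of pairs (interval 97.4 to 99.6), which argues against that. Molecules of 1 library read under the index of the other may give a small and even share, and the smaller copy held a median of 2.83% of the UMIs of a larger copy in the knockout and 1.47% of one in the control library, with a ratio of the 95th to the 5th percentile of 2.38. This stays open, because the matrices hold no barcodes under 500 UMIs or not called as cells, and of 293 cells deep enough for a copy well above that limit only 101 (34.5%, interval 29.0 to 40.2) had one. The biological origin of a shared barcode was not tested, since barcodes carry none.

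N6amt1 kept 18.0% of its control level in the knockout library. A subset of unrecombined cells at the control level predicts 63.4 cells with 2 or more N6amt1 UMIs, and 28 were observed, 0.441 of the prediction (interval 0.293 to 0.638), although the level differed between clusters, with 3.93 CPM in cycling-like cells and 10.9 CPM in cluster 6. The same level in all knockout cells predicts 19.2 such cells. As 28 lay between these predictions, some unrecombined cells beside a low general level were not excluded. Molecules of control cells in the matrix, read under the knockout index, reach only knockout cells whose barcode is also in the control matrix. The filters had removed 163 knockout cells with a larger control copy and kept 6, which held 0 N6amt1 UMIs (upper limit 42.2 CPM). The share of 100% (interval 98.4 to 100) in all other cells was thus largely set by the filters, and no conclusion is drawn from it. Of the N6amt1 UMIs, 170 lay in cells whose barcode was not in the control matrix, which such molecules cannot reach. Control barcodes outside the matrix were not weighed. Transcripts that keep their 3′ end after the deletion, a biological candidate explanation, stay open, because the 229 UMIs carry no read positions in a count matrix.

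The S phase list lay lowest of all lists, with a median log2 ratio of -1.16. A lower share of cycling-like cells alone gave 22.8% of that median (and 102% of that of the G2 and M phase list), too little for the whole pattern. The cycling-like cluster was led by mitotic genes, and control cells of cluster 2 also held S phase transcripts (1914 CPM). Fewer S phase cells are thus not excluded by this share. The shares of all clusters gave 93.6% of the S phase median with cell cycle genes left out of the clustering and 91.0% with them. Within clusters the list went both ways (in control and knockout cells 1472 and 2096 CPM in cluster 0, 4169 and 3030 CPM in the cycling-like one). The lower list may thus lie mostly in which clusters each library held, although most clusters come mainly from 1 library. A trend with transcript length also fell short as the whole cause, since the median relative to genes of like length was -1.07, below the random range. Loss of KMT9alpha (median -1.16), TAM itself and another difference between the cultures or library preparations cannot be told apart. The design has 1 library per group, and by the labels all knockout records and no control records are plus TAM. Any of these differences could underlie the lower list.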

How the results depend on the processing

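Alternatives that left out cells with a barcode in both matrices, their smaller copies, low-depth clusters or colonocyte-like clusters, that took ratios relative to transcript length, or that took the cycling-like class without cell cycle genes were chosen after seeing the data. N6amt1 kept its direction under all 10 alternatives run, with log2 ratios from -2.52 to -2.35. Of 638 higher and 844 lower genes, the counts were 184 and 309 at 50 or more CPM and 222 and 196 at 2-fold, since fewer genes qualify. Without a filter on low genes the counts were 5121 and 3044, since genes of a few UMIs enter. The 13 other alternatives of each count stayed within 1.5 times of it.

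The number of lists below their random range was 5, and 5 to 8 under 18 alternatives, with 8 without colonocyte-like clusters, where the cause was not tested. The number above was 14, and 10 to 14. Of the 19 lists outside, 11 stayed on their side under every alternative, and the others lost it under at least 1, namely the fetal-like, G2 and M phase, colonocyte, fatty acid synthesis, heat shock, Notch, BMP and lysosome lists. In cells at or below the control median G2 and M share (1315 control and 1100 knockout cells), the S phase median was -0.75 and the G2 and M phase median -0.26. The choice of cells by G2 and M phase transcripts brings about the G2 and M phase value in part. For the S phase median the cause was not tested. Under the 17 other alternatives the S phase median stayed between -1.25 and -1.04. Without colonocyte-like clusters the fetal-like median reversed to -0.066 and the colonocyte median to -0.56. Without cells of a shared barcode the colonocyte median reversed to -0.38, and the cause was not tested. That choice dropped 93 of the 198 knockout cells of cluster 7, which was colonocyte-like. Leaving out only the smaller copies of such barcodes kept the median above its random range. The stem cell median ranged from -0.15 to 0.17 and the Wnt median from 0.17 to 0.36. Of all 621 list values under alternatives, 605 moved by less than the spread of their random lists allows, 13 by more, and 3 reversed, as given here.

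Of 18 genes, 6 had a share of cells with a UMI at least 1.5-fold lower in the knockout library, and 6 or 7 under 4 alternatives. Krt20 had one at least 1.5-fold higher, as did Muc2 on only 6 control and 7 knockout cells and Chga on 3 cells of each library. The knockout over control ratio of cycling-like shares was 0.490, and 0.420 to 0.486 under 6 alternatives. The ratio of colonocyte-like shares, 1.82 but not read as a difference because different clusters hold the class, reversed to 0.337 at resolution 1.2 and to 0.265 with each library clustered alone, where 170 and 171 of the 207 knockout cells took the name fetal-like. At resolution 0.4 no cluster was colonocyte-like, so no value exists. Some alternatives named a Paneth-like class, which the main clustering lacked. It held 33.5% of control and 2.77% of knockout cells at resolution 0.4, but 8.33% and 9.18% with each library clustered alone. A fetal-like class held 1.03% and 11.5% at resolution 1.2, and 0% and 12.8% with each library clustered alone. Within cycling-like cells all 33 list medians stayed close when the cell cycle genes were left out. Leaving out a replicate was not possible. No paired analysis was possible because each group is 1 library. Counts limit genes near the floor, such as Chga and Lyz1, and 1 library per group limits every difference.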

Other observations

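The values below came from comparisons within clusters, by transcript length and by chromosome, and the choice of which to give was made after the results were seen.

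The colonocyte-like class differed between the libraries in its clusters as well as in its genes. In the colonocyte-like class, which was mostly cluster 9 in the control and cluster 7 in the knockout library, Clu stood at 207 against 1516 CPM, Sprr1a at 30.2 against 974 CPM, the chemokine gene Ccl5 at 1.31 against 255 CPM (with a UMI in 1.54% and 5.15% of the thinned cells) and Krt20 at 13.3 against 83.4 CPM. Ascl2 stood at 257 against 20.4 CPM, Cdx2 at 195 against 33.2 CPM and N6amt1 at 35.6 against 3.48 CPM. Fetal-like and YAP targets had a median log2 ratio of 1.09 there (percentile 100), with 14 of 21 higher and 1 lower, and oxidative phosphorylation genes one of -0.56 (percentile 0), with 21 of 44 lower. MAPK and EGFR feedback genes had a median of 0.59, and cytosolic ribosomal protein genes one of -0.43. In cluster 7 alone the fetal-like genes summed to 18871 CPM in the 31 control cells and 17963.5 CPM in the knockout cells. In the control cells of cluster 9 they summed to 8277 CPM. By this sum the clusters differed more than the libraries did within cluster 7. Abundant genes weigh most in a sum, which is not the list median. Single members still differed between the libraries within cluster 7, with Sprr1a at 137 against 1016 CPM and Clu at 753 against 1588 CPM.

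In the cycling-like cells, p53 targets were lower in the knockout library, with a median log2 ratio of -0.71 (percentile 0) and 14 of 23 measured members lower and 0 higher. Bbc3, which encodes the cell death protein PUMA, stood at 195 against 65.0 CPM, Cdkn1a at 1053 against 739 CPM and Gdf15 at 749.7 against 504 CPM. Estrogen and xenobiotic response genes had a median of -1.42 there, with 5 of 7 lower. Among them was Cyp1a1, a target of the aryl hydrocarbon receptor, at 49.3 against 12.5 CPM. Whether TAM, by which the libraries also differ, bears on this list was not tested. Glycolysis and hypoxia genes had a median of 0.43 (percentile 100), with 7 of 22 higher, and Hk2 stood at 27.5 against 68.0 CPM. Cytosolic ribosomal protein genes had a median of 0.15 (percentile 100). The Wnt antagonist gene Dkk2 stood at 1.76 against 18.7 CPM and Mmp7 at 111 against 335 CPM.

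Cells whose barcode occurred in both matrices were 167 of the control cells (6.35%) and 324 of the knockout cells (21.9%), and they were not a random part. In the knockout library Car1 stood at 919 CPM in them and 14.2 CPM in the rest, Muc3 at 61.2 against 2.71 CPM and Sprr1a at 485 against 138 CPM, while N6amt1 stood at 5.88 against 6.22 CPM. They made up 47.0% of cluster 7, 37.8% of cluster 6, 29.9% of cluster 1 and 11.9% of cluster 3 among knockout cells.

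With genes split into 10 bins of transcript length, the median log2 ratio ran from -0.20 in the bin of 1190 to 1616 nucleotides to 0.18 in the bin of the longest transcripts (6317 nucleotides or more). Medians by chromosome ran from -0.13 on chromosome 17 to 0.02 on chromosome 18.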
